A study of Mus with 6 samples.

How the data were processed

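Ribosome-bound RNA from whole mouse brain was compared between 2 control samples and 4 samples labelled IRKO, all of them RiboTag immunoprecipitates that the labels assign to microglia. Per the submitters' processing notes, reads were handled with Bowtie2 and the mouse build GRCm38.p6. The counting tool, the annotation, the strandedness of the library kit and the normalization tool are not given in the sources used here. The values that the authors deposited are a signal per gene, read counts of each gene divided by 1 size factor per sample, per the file headers and the values themselves. In each sample they were whole multiples of the smallest value above 0, and 100% of values came out whole within 0.05 reads. The size factors equalled the median-of-ratios factors recomputed from the recovered reads, with a ratio of 1 in all 6 samples. In IRKO replicate 1 the value of a single read was 0.991, too near 1 for a formal step test to tell it from rounding, so count-based tests were also run on the other 5 samples.

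The recovered depth was 16883098 and 19010680 reads in the controls and 13858978 to 14568773 in the IRKO samples. The fixed design took limma on the deposited normalized values as the main test, and this was kept. Genes with a value of at least 10 in at least 2 samples were tested, which left 14698 of 18887 genes, and 18542 of the symbols matched the RefSeq gene table of GRCm38.p6, from which coordinates were taken. Values were transformed as log2(value + 1), with a pseudocount of 1, so that fold changes understate the change of genes with low values. A linear model with IRKO minus control as its contrast was fitted to all 6 samples with limma 3.58.1 in R 4.3.3, with moderated variances and a mean-variance trend. P-values are two-sided and Benjamini-Hochberg adjusted, with a threshold of 0.05. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. A chi-square statistic of the reads per degree of freedom lay between 17.5 and 38.6 for every pair of samples within a group, so no library was counted as a duplicate of another.

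Lists of genes for cell types and pathways were written from textbook knowledge. For each list the number of tested members higher or lower was counted with p-values adjusted over all genes and again adjusted over the list alone. Lists were tested against the other genes with limma's camera at a preset correlation between genes of 0.01, adjusted over the 24 lists with tested members. Some genes belong to several lists, such as 15 of the 50 tested lysosome and autophagy genes and 11 of the 36 FOXO targets. Results of such lists are not independent. A list of mitochondrially encoded genes was matched by name only and had no member among the rows analysed here. Sex-linked genes were tabulated per sample without a test: the Y-linked gene Ddx3y was read in all 6 libraries, at normalized counts of 324 and 370 in the controls and 358 to 557 in the IRKO samples.

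The genes named were fixed by rule: Insr; among genes past the threshold whose 4 IRKO values all lay on the same side of both control values, the 12 largest rises and the 12 largest falls with a symbol that is not that of a predicted gene; in each list up to 4 members with the smallest p in its larger direction and up to 2 in the other; and the 10 genes with the highest mean value. A few genes that the rule picks are not reported here, though the list counts and medians include them. Groups, lists, this rule, the tests and most alternatives were fixed before the data were examined. The alternatives were pseudocounts of 0.5 and 5, no filter and a filter at 50, TMM scaling, quantile normalization, no variance trend, sample weights, a test against a fold of 1.2, a replicate block, leaving out each sample in turn, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, camera with an estimated correlation, and fry. Scaling each library to an equal mean of the homeostatic microglia list, the count-based tests without IRKO replicate 1, and leaving out each sample in turn for bounds and ratios were added after the data had been seen. A list of 30 liver markers and the lists of connective tissue and bone, glutathione and antioxidant, and transmitter handling genes were also written after the data had been seen.

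For genes with 0 reads in a group, a lower bound of the fold was computed against a floor of 3 reads over the group, and for genes with 1 to 3 reads the ratio is given with a 95% counting interval. Such bounds and intervals cover counting error only. Paralogs such as the haemoglobin, Serpina1, Mup, Pcdha and Entpd4 genes may share reads, and their separate values are uncertain. The fit was tested on simulated data for this comparison, with 14698 genes in each of 5 runs. It called 16.5% of genes changed 1.5-fold, 63.9% of those changed 2-fold and 91.9% of those changed 4-fold, and 7.9% of its calls fell on unchanged genes. In the same simulations camera called the changed list in 5 of 5 runs and none of 115 unchanged lists, with the preset and with the estimated correlation. In these runs genes varied independently, few genes changed and the true size factors were used, unlike in the data. They therefore cannot show how either camera setting acts on correlated genes, nor how the fit acts under a wide shift.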

Results

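RiboTag profiling uses a tagged ribosomal protein, expressed in a chosen cell type, to precipitate that cell type's ribosomes with the mRNA bound to them. Here the labels give microglia, the resident immune cells of the brain, as the cell type and whole brain as the tissue. The data comprised 2 control precipitates and 4 precipitates labelled IRKO with a knockout genotype, read here as loss of the insulin receptor from the study's title on insulin signalling in microglia. Each library held 13858978 to 19010680 recovered reads, and 14698 genes were tested. The comparison asks how ribosome-bound transcripts in precipitates labelled as microglia differ when insulin signalling is lost, with uptake of amyloid and inflammatory genes named in the study's title. No input or unbound library is among the samples, so enrichment of microglial RNA was not measured. Differences between the groups may therefore reflect cell content as well as genotype.

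Insr, which encodes the insulin receptor and lies on chromosome 8 from 3150922 to 3279649 in GRCm38.p6, was lower in every IRKO library than in both controls. Its normalized count was 548 ± 23.4 (SD, n = 2) in the controls and 338 ± 33.5 (SD, n = 4) in IRKO. The log2 change was −0.70 ± 0.135 (SE), with a limma adjusted p of 0.00211. With the libraries scaled to an equal mean of the homeostatic microglia list, the log2 change was −2.13, where the median of all genes was −1.40. The deposited values are sums over a gene, so loss of some exons could not be seen separately.

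Much of the measured transcriptome differed between the groups. Astrocyte genes were far lower in IRKO and microglial genes higher, as in Aldh1l1, a folate enzyme used as an astrocyte marker, at −4.66 ± 0.144 (log2, SE), and Tgfbr1, a TGF-beta receptor, at 1.97 ± 0.154 (n = 2 against 4 for both). At a limma adjusted p under 0.05, 8173 genes (55.6%) differed, 3911 higher and 4262 lower in IRKO, and 3749 of them changed at least 2-fold. Falls reached further than rises: 372 genes fell and 21 rose at least 8-fold. For 67.6% of genes the 4 IRKO values lay on the same side of both control values, against 13.3% by chance. The split depended on the scaling. Scaling to the homeostatic microglia list moved the median change of all genes to −1.40, with 76 genes higher and 11641 lower, while quantile normalization moved it to 0.12, with 4527 higher and 3559 lower, and TMM to 0.03. In the first of these scalings 30 named genes changed direction and 49 no longer passed limma's test, 22 of them among those 30. The other 27 did not change sign but shrank, some to nearly 0, as Ctsc (0.02), Abcg1 (0.003), Txnip (0.08) and Irf8 (0.08). Among the 27 were the rises below of Siglech, Ctsc, Tyrobp, Cd52, Vav1, Ctss, Mrc1, H2-DMb1, Tgfb1, Irf8, Parp14, Pik3cd, Txnip, Klf4, Abcg1, Cd79b, Pvalb, Pdgfra and Pecam1. List medians in that scaling are given beside the main ones.

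**Figure D1:**
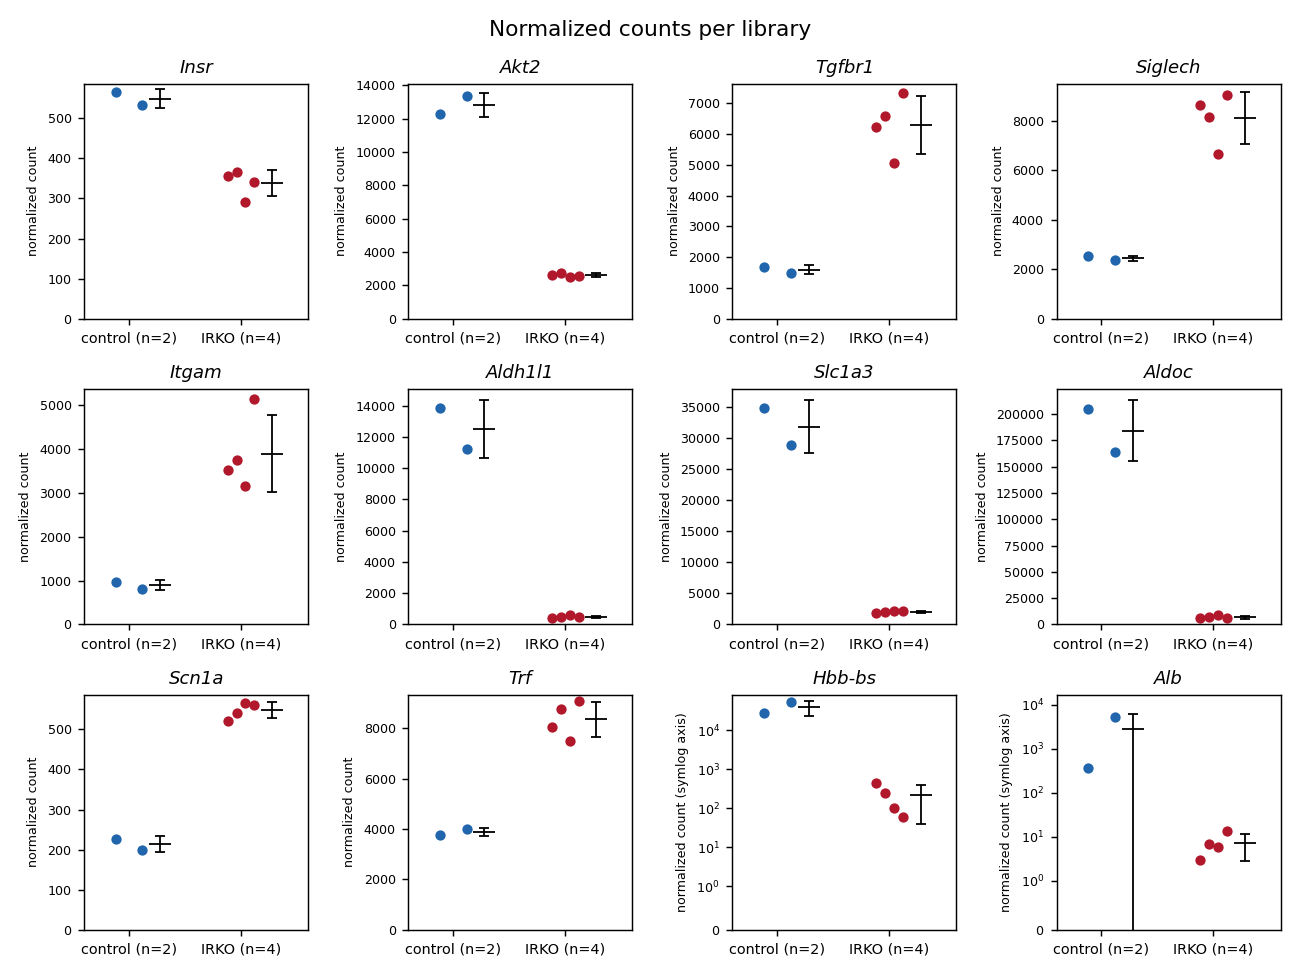
Normalized counts of 12 genes in each library, with control libraries in blue (n = 2), IRKO libraries in red (n = 4), and the group mean and SD in black, on linear axes except for Hbb-bs and Alb, whose axes are symlog and where the SD bar of Alb is clipped at 0. Insr was lower in all 4 IRKO libraries (338 against 548 on average) and Aldh1l1, Slc1a3 and Aldoc fell far more, while Tgfbr1 and Itgam rose, as did Siglech, Scn1a and Trf in the deposited scaling but not with libraries scaled to the homeostatic microglia list (0.29 with a limma adjusted p of 0.236, −0.07 and −0.33). Tgfbr1, Itgam and Siglech belong to that list, whose members this scaling centres near 0 by construction.

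All 25 tested astrocyte markers fell, with a median log2 change of −3.89 and a range from −5.13 to −2.07 (25 fell adjusted over the list alone), and a median of −5.33 scaled to the microglia list. Slc1a3, a glutamate transporter, dropped from 31900 ± 4310 (SD, n = 2) to 2007 ± 132 (SD, n = 4). Cldn10, a claudin, changed by −4.71 ± 0.147 (log2, SE) and Acsl6, which activates long-chain fatty acids, by −3.69 ± 0.135. Camera placed the list below the other genes (adjusted p = 3.19e-14), a call that was lost at adjusted p = 0.403 with an estimated correlation. The genes with the highest means across libraries included several that astrocytes express strongly. Aldoc (−4.77 ± 0.196), Apoe (−4.07 ± 0.250), Slc1a2 (−3.89 ± 0.187), Cpe (−3.76 ± 0.191), Glul (−3.15 ± 0.223) and Ckb (−2.66 ± 0.195) all fell, whereas Cst3 (−0.44 ± 0.306) and Ptgds (0.17 ± 0.579) did not pass limma's test. Cst3 passed with edgeR (adjusted p = 0.0445) and DESeq2 (0.00426) and stood at 0.88 under quantile normalization. The 10 most abundant genes of each library took 12% and 11.2% of the control totals and 4.68 to 6.64% of the IRKO totals.

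Of 38 homeostatic microglia genes, 36 rose, Jun fell and 1 did not pass, with the same counts adjusted over the list alone. The median log2 change was 1.5, and 0.07 once libraries were scaled to this list. Itgam, an integrin of the complement receptor, rose 4.29-fold, from 897 ± 115 (SD, n = 2) to 3901 ± 873 (SD, n = 4). Gpr34 and Siglech, both microglial surface receptors, rose 3.88-fold and 3.29-fold. Siglech no longer passed limma's test with libraries scaled to this list (adjusted p = 0.236), but that scaling centres the list's own members near 0 by construction. Jun, an immediate early transcription factor, changed by −0.43 ± 0.127, and lost its call without control replicate 1 (−0.25, limma adjusted p = 0.174) and under quantile normalization (−0.24, limma adjusted p = 0.139). The camera adjusted p was 2.79e-11, and the call was lost at adjusted p = 0.521 with an estimated correlation.

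As deposited, most neuronal markers moved the other way from astrocyte markers. Among 33 tested, 25 rose, 1 fell and 7 did not pass (25 and 1 adjusted over the list alone), and the median was 0.99 as deposited but −0.44 with libraries scaled to the microglia list. Pvalb, a calcium buffer of interneurons, rose 3.08-fold and Stmn2, a neuronal microtubule regulator, 2.36-fold, the latter turning to −0.19 in that scaling. Tph2, which makes serotonin, fell (−2.31 ± 0.661), and lost its call without control replicate 2 (−1.92, limma adjusted p = 0.128). Camera gave an adjusted p of 2.96e-06 for the neuron list, lost at adjusted p = 0.521 with an estimated correlation.

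Other brain cell types were mixed. Of 25 oligodendrocyte markers 11 rose and 5 fell (11 and 5 adjusted over the list alone), with a median of 0.77 (−0.67 scaled to the microglia list). That median was 0.53 without control replicate 2 and 0.99 without control replicate 1. For these markers camera's adjusted p was 0.0968, or 0.0312 without IRKO replicate 1. Trf, which encodes transferrin, rose 2.15-fold as deposited and stood at −0.33 in that scaling, while Olig1, a transcription factor of the lineage, fell (−1.93 ± 0.244). Of 12 oligodendrocyte precursor genes 5 rose and 3 fell (5 and 3 adjusted over the list alone). Their median was 0.56 as deposited, 0.29 without control replicate 2 and −0.87 scaled to the microglia list, and camera pointed up (adjusted p = 0.637) where fry pointed down (adjusted p = 0.0344). Pdgfra, a growth factor receptor of these precursors, rose 3.33-fold and Cspg5, a proteoglycan, fell (−3.63 ± 0.134). Endothelial and mural genes rose in 13 of 27 cases and fell in 3 (13 and 3 adjusted over the list alone), with a median of 0.72, or −0.70 scaled to the microglia list. For them camera's adjusted p was 0.00571, lost at adjusted p = 0.521 with an estimated correlation. Pecam1, an endothelial adhesion molecule, rose 3.01-fold, and Notch3, a receptor of mural cells, fell (−2.78 ± 0.290).

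None of 14 choroid plexus and ependyma genes rose and 8 fell (8 adjusted over the list alone), with a median of −1.94, or −3.35 scaled to the microglia list and −1.26 without control replicate 2. Foxj1, a regulator of motile cilia, changed by −2.22 ± 0.301 and Rarres2, which encodes chemerin, by −2.81 ± 0.161. The camera adjusted p of 0.0108 became 0.189 without control replicate 2, and adjusted p = 0.528 with an estimated correlation. Border macrophage and monocyte genes rose in 5 and fell in 4 of 17 cases (5 and 4 adjusted over the list alone). Mrc1, the mannose receptor, rose 4.18-fold and Cd38, an NAD hydrolase, fell (−2.86 ± 0.422). The median of this list was 0.22 as deposited, −0.96 with the stricter filter and −1.13 scaled to the microglia list, with −0.26 without control replicate 2 and 0.89 without control replicate 1, and the camera adjusted p was 0.357.

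**Figure D2:**
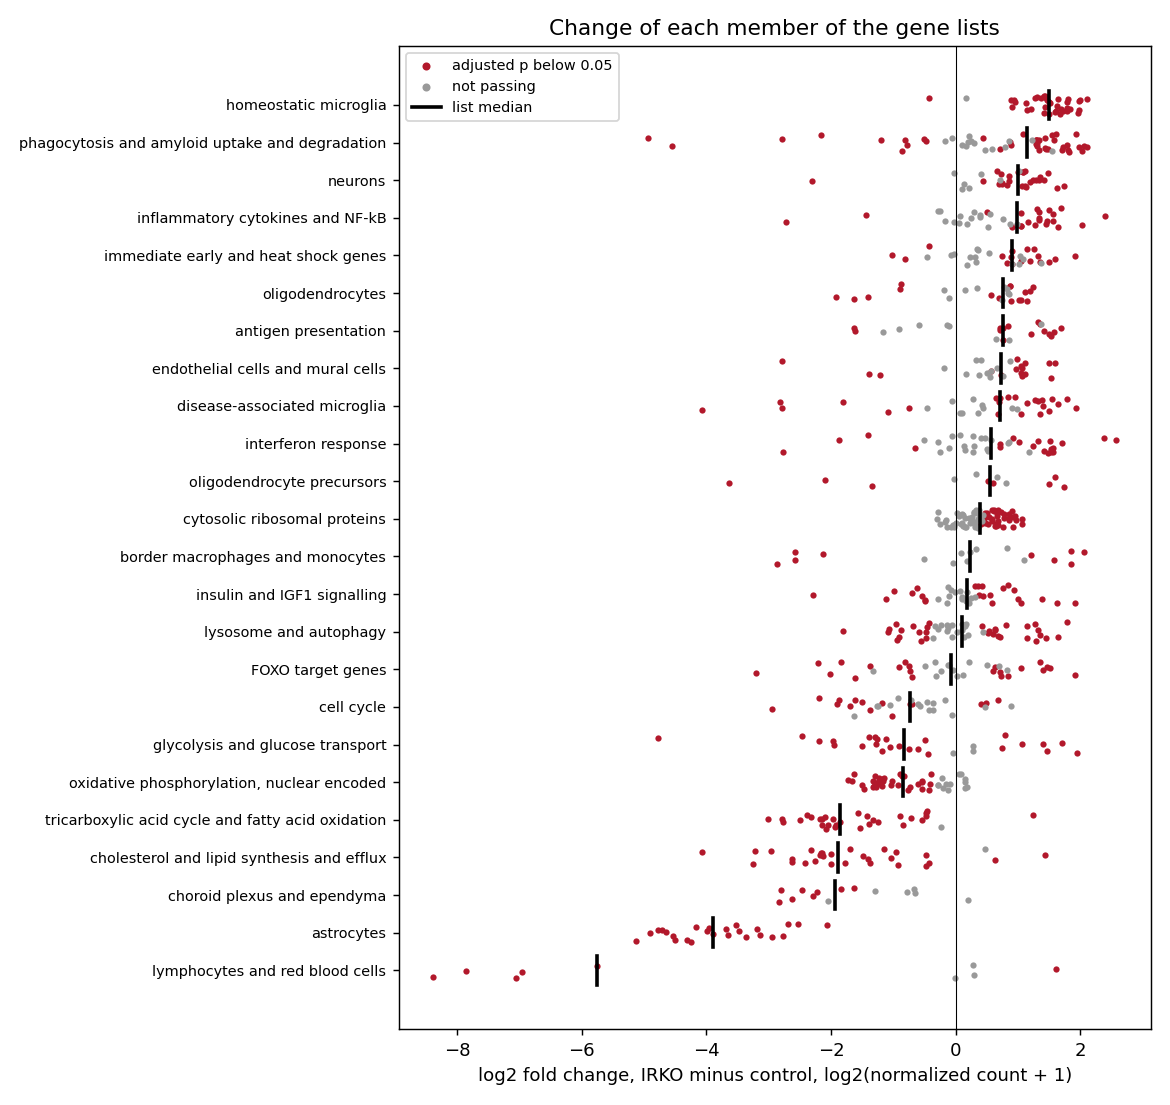
Log2 fold change, IRKO minus control, of every tested member of the 24 gene lists on the log2(normalized count + 1) scale, with red points for genes past a limma adjusted p of 0.05, grey points for the others and a black bar at the list median. Astrocyte markers lie between −5.13 and −2.07 and homeostatic microglia genes centre on 1.5 in the deposited scaling, and 14 of the 15 medians above 0 turn negative with libraries scaled to the homeostatic microglia list, as the FOXO target median turns positive under quantile normalization.

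Blood and liver transcripts formed the largest falls. The haemoglobin genes and Alas2, the first enzyme of haem synthesis in erythroid cells, summed to 75520 and 161600 normalized counts in the controls and to between 243.5 and 2132 in IRKO, a ratio of 126 between the group means that was 80 without control replicate 2 and 216 without IRKO replicate 1. Hbb-bs fell from 39320 ± 16600 (SD, n = 2) to 213 ± 174 (SD, n = 4), and Hba-a1, Hba-a2 and Hbb-bt fell with it, though these paralogs may share reads. Serpina3k (at least 882-fold), Serpina1e (at least 752-fold), Mup10 (at least 555-fold), Gc (at least 381-fold) and Fgb (at least 366-fold), which encode secreted liver proteins, had 0 reads in IRKO. Control replicate 2 carried most of this size: Serpina3k had 81.0 normalized counts in control replicate 1 and 1137 in replicate 2, and without replicate 2 the bounds were 110, 78, 64.2, 42.8 and 52 in the same order. Alb, the gene for serum albumin, fell by 7.51 on the log2 scale, with 360 and 5125 normalized counts in control replicates 1 and 2. Serpina1c and Mup22 were the other named falls, and the Serpina1 and Mup genes are paralogs whose separate values are uncertain. In the list of lymphocyte and red blood cell genes 9 of 23 passed the filter, and the 5 that fell were the haemoglobin genes and Alas2. No tested lymphocyte gene fell. Cd79b, part of the B cell receptor, rose 3.05-fold and the other 3 did not pass (5 falls and 1 rise adjusted over the list alone). The list median was −5.76, or −7.13 scaled to the microglia list and −0.68 with no filter on low values, with a camera adjusted p of 0.152 (0.0395 with no filter). Astrocyte markers, at a median of −3.89, were higher in the same 2 control libraries.

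**Figure D3:**
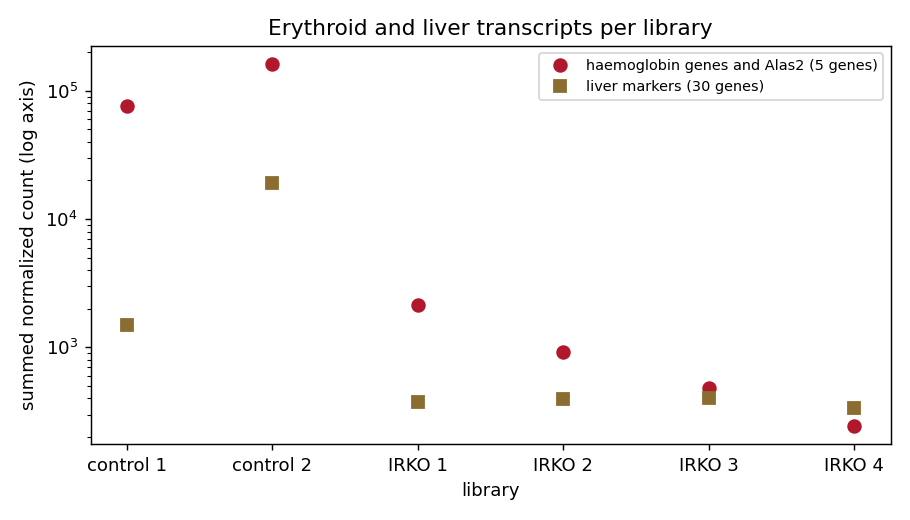
Summed normalized counts per library, on a log axis, of 5 erythroid genes (circles) and 30 liver markers (squares). Both sums were highest in control replicate 2, at 161600 and 19170, and liver markers summed to 1495 in control replicate 1 and to 337 to 400 in the IRKO libraries, where Rbp4 alone gave 212 to 306 (112 in control replicate 1) and the other 29 markers 84.2 to 188.

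The named genes with the largest rises were Entpd4, Pcdha10, Ccr6, Bglap, Pcdha3, Mmp3, Lypd2, Lox, Gvin1, Postn, Mc5r and Bcl2a1d. Entpd4 (at least 77.4-fold) and Pcdha10 (at least 48.7-fold) had 0 reads in the controls, and the bounds were 35.8 and 22.5 without control replicate 2. However, Entpd4 may share reads with its near-identical copy Entpd4b, and Pcdha10 overlaps Pcdha3 on chromosome 18. Entpd4 and Entpd4b together differed by a ratio of 1.17 and the 14 Pcdha genes together by 1.86, so the single values are uncertain. Ccr6, a chemokine receptor, had 4.34 ± 3.40 (SD, n = 2) normalized counts in the controls and 370 to 601 in 3 IRKO libraries, but 6.80 in IRKO replicate 3. Postn and Lox, which act in the extracellular matrix, rose by 3.35 ± 0.855 and 3.55 ± 0.890 (2.63 and 2.80 without IRKO replicate 3), and Mc5r, a melanocortin receptor, by 3.25 ± 0.521. Lypd2 had a ratio of 23.6 (95% counting interval 6.35 to 197, for counting error only), from 2 reads in the controls, both in replicate 1. The ratio was 14.1 without IRKO replicate 1 and 10.9 without control replicate 2, and without control replicate 1 Lypd2 was at least 8.44-fold higher in IRKO. Without control replicate 2 the limma calls of Ccr6 (adjusted p = 0.131), Bglap (0.0604), Mmp3 (0.0766), Lox (0.0666), Gvin1 (0.264) and Postn (0.0760) were lost, and without control replicate 1 those of Ccr6 (0.0624) and Lox (0.0510). Gvin1 also lost its call without each of IRKO replicates 2, 3 and 4 (0.0548 to 0.0797), and with edgeR (0.121) and DESeq2 (0.339).

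Of 38 insulin and IGF1 signalling genes 15 rose and 8 fell, and 15 and 9 adjusted over the list alone. Akt2, the kinase isoform central to insulin action, fell 4.89-fold (12810 ± 725, SD, n = 2, against 2621 ± 116, SD, n = 4), and Foxo1, a transcription factor restrained by insulin signalling, fell 2.18-fold. Inpp5d, a lipid phosphatase of myeloid cells, rose 3.77-fold and Pik3cd, a leukocyte PI3-kinase subunit, 3.08-fold. The median was 0.17 as deposited, 0.42 under quantile normalization and −1.26 scaled to the microglia list, and camera's adjusted p was 0.172 (0.0404 under quantile normalization). As deposited, FOXO target genes split evenly, with 11 up and 11 down of 36 (12 and 14 adjusted over the list alone) and a median of −0.08 that became −1.51 scaled to the microglia list and turned to 0.11 under quantile normalization and 0.01 without IRKO replicate 4. Pdk4, which restrains glucose oxidation, fell (−3.21 ± 0.314) and Txnip, a thioredoxin-binding protein, rose 2.85-fold, with a camera adjusted p of 0.828 for the list. For comparison, the medians of the marker lists in these libraries were −3.89 for astrocytes, 0.99 for neurons and 1.5 for homeostatic microglia. The log2 changes of Akt2 (−2.29) and Pdk4 (−3.21) lay within the range of the astrocyte markers (−5.13 to −2.07), and that of Foxo1 (−1.13) lay above it. Whether the transcripts that fell came from microglia was not measured.

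Among 3 lists of energy metabolism, more genes fell than rose in IRKO. In the tricarboxylic acid cycle and fatty acid oxidation list 29 of 31 genes fell and 1 rose (29 and 1 adjusted over the list alone), with a median of −1.85, or −3.29 scaled to the microglia list. Hadh, which acts in fatty acid oxidation, fell 6.91-fold and Cs, citrate synthase, 4.16-fold, while Ppargc1b, a coactivator of mitochondrial genes, rose 2.37-fold as deposited and stood at −0.18 with libraries scaled to the microglia list. The list's camera adjusted p was 1.42e-10, lost at adjusted p = 0.123 with an estimated correlation. Of 46 nuclear-encoded oxidative phosphorylation genes 33 fell and none rose (33 adjusted over the list alone), with a median of −0.85, or −2.28 in that scaling and −0.53 under quantile normalization, and the other 13 did not pass. Uqcrfs1 of complex III fell 3.31-fold and Ndufs1 of complex I 3.18-fold (camera adjusted p = 1.93e-07, and adjusted p = 0.528 with an estimated correlation). Glycolysis and glucose transport genes fell in 18 and rose in 7 of 28 cases (18 and 7 adjusted over the list alone), with a median of −0.83, or −2.27 in that scaling and −0.39 under quantile normalization. Eno1 fell 4.56-fold and Pfkm 5.56-fold, whereas Hk2, a hexokinase, rose 3.83-fold. For this list, camera's adjusted p of 0.0172 was lost at adjusted p = 0.528 with an estimated correlation. The astrocyte marker median of −3.89 lay below all 3 of these medians, and the neuron (0.99) and microglia (1.5) medians above them, all as deposited.

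In the cholesterol and lipid list 27 of 30 genes fell and 2 rose (27 and 2 adjusted over the list alone), with a median of −1.89, or −3.32 scaled to the microglia list. Srebf1, a regulator of lipid synthesis, fell 9.37-fold, Scd2, a desaturase, 9.56-fold and Msmo1 of the cholesterol pathway 5.33-fold. Abcg1, a sterol exporter, rose 2.70-fold as deposited, and with libraries scaled to the microglia list it no longer passed limma's test (adjusted p = 0.989). With camera the adjusted p was 1.12e-08, lost at adjusted p = 0.0577 with an estimated correlation. Beside this group, astrocyte markers had a median of −3.89, neurons of 0.99 and homeostatic microglia of 1.5.

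Phagocytosis and amyloid uptake genes rose in 30 and fell in 10 of 54 cases (31 and 10 adjusted over the list alone), with a median of 1.15, or −0.23 scaled to the microglia list. Cd14, a pattern recognition receptor, rose 4.07-fold and Vav1, a regulator of actin signalling, 3.53-fold. Clu, which encodes clusterin, fell from 106400 ± 28100 (SD, n = 2) to 3446 ± 609 (SD, n = 4), and Mfge8, a bridging protein for apoptotic cells, fell 23.4-fold. Camera's adjusted p was 0.000333, lost at adjusted p = 0.528 with an estimated correlation. Disease-associated microglia genes rose in 18 and fell in 6 of 34 cases (19 and 6 adjusted over the list alone). Tyrobp, the adaptor of Trem2, rose 2.90-fold and Cd52 3.12-fold, while Apoe fell 16.8-fold and Fabp5, a lipid chaperone, 7.10-fold. Their median was 0.71, or −0.73 scaled to the microglia list, and camera's adjusted p of 0.0198 became 0.0688 without control replicate 2 and adjusted p = 0.528 with an estimated correlation. Of the tested members, 13 of the 54 phagocytosis genes and 16 of the 34 disease-associated genes also belong to another list, so the lists are not independent. The homeostatic microglia median of 1.5 exceeded both list medians, and the astrocyte median was −3.89. The log2 changes of Clu (−4.94), Mfge8 (−4.55), Apoe (−4.07) and Fabp5 (−2.83) lay within the range of the astrocyte markers (−5.13 to −2.07). Whether these transcripts came from microglia was not measured.

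Inflammatory cytokine and NF-kB genes rose in 21 and fell in 2 of 39 cases (22 and 2 adjusted over the list alone), with a median of 0.99, or −0.44 scaled to the microglia list. Tlr7, an endosomal receptor for RNA, rose 4.08-fold and Tgfb1 2.94-fold, whereas Il18 fell 6.61-fold and Tlr3 2.70-fold. Camera's adjusted p was 0.000752, lost at adjusted p = 0.528 with an estimated correlation. Interferon response genes rose in 16 and fell in 4 of 39 cases (16 and 4 adjusted over the list alone), with a median of 0.56, or −0.85 in that scaling. Parp14 rose 3.26-fold and Irf8, a myeloid transcription factor, 2.85-fold, and Ifit3b fell 6.84-fold. This list had a camera adjusted p of 0.00571, lost at adjusted p = 0.521 with an estimated correlation. Antigen presentation genes rose in 13 and fell in 2 of 23 cases (14 and 2 adjusted over the list alone). H2-DMb1, a class II chaperone, rose 2.99-fold and the class II gene H2-Eb1 fell (−1.64 ± 0.464), and lost its call without control replicate 1 (−1.45, limma adjusted p = 0.115) or 2 (−1.82, limma adjusted p = 0.0582). The list's median was 0.76, or −0.67 scaled to the microglia list, and camera's adjusted p of 0.0162 became 0.0549 without IRKO replicate 4 and adjusted p = 0.528 with an estimated correlation. Against these lists stood marker medians of 1.5 for homeostatic microglia and −3.89 for astrocytes.

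Lysosome and autophagy genes went both ways, with 18 up and 14 down of 50 (19 and 14 adjusted over the list alone) and a median of 0.10, or −1.33 scaled to the microglia list, 0.33 under quantile normalization and 0.03 without control replicate 2 (camera adjusted p = 0.503, and 0.0423 under quantile normalization). Ctss, a cathepsin of microglia, rose 3.45-fold and Ctsc, another cathepsin, 2.72-fold, and Cd63, a tetraspanin, fell 3.52-fold. Psap, among the most abundant genes, was lower as deposited (−0.69 ± 0.214) and higher under quantile normalization (0.60), and lost its limma call without control replicate 1 (adjusted p = 0.225), control replicate 2 (0.0652) or IRKO replicate 2 (0.0541), or with no filter (0.0829). Cytosolic ribosomal protein genes rose in 36 of 77 cases and fell in none (35 adjusted over the list alone), with a median of 0.39, or −1.04 scaled to the microglia list and 0.73 under quantile normalization. Fau rose 2.09-fold and Rps28 2.08-fold as deposited and both turned negative in that scaling (−0.37 and −0.38), and copies of ribosomal protein genes may share reads. Camera's adjusted p was 7.17e-06, lost at adjusted p = 0.528 with an estimated correlation. Astrocyte markers were at −3.89, neurons at 0.99 and homeostatic microglia at 1.5 (medians) beside both lists.

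Immediate early and heat shock genes rose in 14 and fell in 3 of 32 cases (14 and 3 adjusted over the list alone), with a median of 0.90, or −0.54 scaled to the microglia list. That median fell to 0.20 without control replicate 1 and was 1.15 without control replicate 2. Klf4, a transcription factor, rose 3.78-fold and Hspa5, a chaperone of the endoplasmic reticulum, fell 2.04-fold. Camera's adjusted p of 0.00752 became 0.0967 without control replicate 1 and adjusted p = 0.528 with an estimated correlation. Cell cycle genes fell in 12 and rose in 3 of 31 cases (12 and 3 adjusted over the list alone), with a median of −0.73, or −2.16 scaled to the microglia list and −1.11 without IRKO replicate 3. Ccnd2, a cyclin, fell 3.68-fold and Rrm2, needed for nucleotide synthesis, 7.69-fold, while Ccnd1 was higher as deposited (0.41 ± 0.115), lower scaled to the microglia list (−1.03), and not called without control replicate 2 (0.30, limma adjusted p = 0.122). The cell cycle call, at a camera adjusted p of 0.0171, became 0.103 without control replicate 1 and adjusted p = 0.528 with an estimated correlation. The marker medians of astrocytes (−3.89), neurons (0.99) and homeostatic microglia (1.5) apply to these lists too.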

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

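The search for a single library standing apart was applied to the 161 named genes, 24 list means and the read totals, with the named genes chosen by their values. In each of these 186 sets of 4 IRKO values on the log2 scale, the gap between the outermost library and its neighbour was divided by the whole range. Chance puts about 1 in 20 sets past the critical value, or about 9.3 here, and 23 passed it. Of these, 14 concerned IRKO replicate 3, 6 replicate 4, 2 replicate 2 and 1 replicate 1, and since genes of the same list move together they are not independent.

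In IRKO replicate 3 some lists and genes stood low and others high. The homeostatic microglia list had a mean log2 value of 11.8 there against 12.2 in each of the other IRKO libraries (gap over range 0.916), and the lysosome and autophagy list 11.3 against 11.4 to 11.5 (0.842). Of the 24 list means, 11 were highest among the IRKO libraries in this one and 6 lowest, and none of the 11 passed the critical value. Those highest in it included astrocytes (10.2 against 9.82 to 10.1), neurons (11.5 against 11.1 to 11.3), oligodendrocytes (9.99 against 9.10 to 9.60), oligodendrocyte precursors, choroid plexus and ependyma (6.34 against 4.44 to 5.74), interferon response (7.20 against 6.79 to 7.15), border macrophages and monocytes (5.49 against 5.22 to 5.37), cell cycle, ribosomal proteins, glycolysis and oxidative phosphorylation. Ccr6 had a normalized count of 6.80 against 370 to 601 (0.889), close to the 6.75 of control replicate 1. Tyrobp stood at 4920 against 6060 to 6110 (0.964), Tlr4 at 196 against 290 to 296 (0.954), Vav1 at 1860 against 2520 to 2600 (0.910) and H2-T23 at 1540 against 2300 to 2440 (0.877). Irf8 (0.872), Cd86 (0.843), Pik3cd (0.838), Zfp36 (0.873) and Cat (0.991) were also lowest in this library. Cldn10 (262 against 194 to 198, 0.940) and Cox6a1 (0.967) were highest in it.

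In IRKO replicate 4, Fau (15900 against 20800 to 21400, 0.901), Ccnd2 (0.875), Sdha (0.845) and Uqcrfs1 (0.835) were low and Tlr7 was high (1500 against 884 to 941, 0.882). Mup22 had 3.90 normalized counts there and 0 in the other IRKO libraries, which gives a gap over range of 1 from a few reads. Bcl2a1d was low in IRKO replicate 2 (57.2 against 200 to 251, 0.846) and Lck high in it (0.883), and Hadh was high in IRKO replicate 1 (587 against 449 to 468, 0.841).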

How the results depend on the processing

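Scaling to the homeostatic microglia list and the count-based tests without IRKO replicate 1 were chosen after seeing the data. Insr stayed lower and past the threshold under every setting run, from −2.13 (microglia list scaling) to −0.562 (quantile normalization), and from −0.743 to −0.629 when a library was left out. The number of changed genes ranged from 5746 (test against a fold of 1.2) to 11717 (microglia list scaling), with 8068 for edgeR and 7993 for DESeq2 on the recovered reads, 7705 and 7581 without IRKO replicate 1, and 6050 to 7820 with a library left out, lowest without control replicate 1. Leaving out a control leaves 1 sample in that group, which is then assumed to vary like the IRKO samples. The replicate numbers 1 and 2 occur in both groups, and deviations of libraries sharing a number correlated at −0.082 and 0.079. With 2 controls their deviations mirror each other, so both values rest on the same control difference. They show no clear pairing by number but cannot exclude a shared batch. Numbers 3 and 4 occur only in IRKO, so with the replicate block those libraries do not affect the estimate. That setting compares replicates 1 and 2 of each group, and gave 6935 changed genes and an Insr change of −0.600. The cause of each change below was not tested, except that scaling to the microglia list shifts all genes by construction. That scaling gave 76 genes higher and 11641 lower. It reversed the medians of antigen presentation (−0.670), border macrophages (−1.13), ribosomal proteins (−1.04), disease-associated microglia (−0.727), endothelial cells (−0.701), immediate early genes (−0.535), inflammatory cytokines (−0.436), insulin signalling (−1.26), interferon response (−0.853), lysosome (−1.33), neurons (−0.440), oligodendrocyte precursors (−0.870), oligodendrocytes (−0.665) and phagocytosis (−0.232). It also reversed 30 named genes: H2-T23 (−0.0829), Ccnd1 (−1.03), Stmn1 (−0.749), Lipa (−0.798), Rps28 (−0.375), Fau (−0.368), Rpl34 (−0.580), Rps12 (−0.532), Cd83 (−0.0317), Cd68 (−0.0824), Egfl7 (−0.452), Esam (−0.353), Ly6c1 (−0.369), Klf6 (−0.381), Slc16a3 (−0.0136), Zfp36 (−0.104), Rhob (−0.610), Tlr4 (−0.123), Pik3cb (−0.437), Rps6kb1 (−0.677), Psmb9 (−0.00641), Scn1a (−0.0697), Celf4 (−0.360), Stmn2 (−0.192), Tnr (−0.913), C1ql1 (−0.826), Trf (−0.327), Cldn11 (−0.241), Sox10 (−0.539) and Ppargc1b (−0.182). Quantile normalization reversed Psap (0.602) and the FOXO target median (0.107), which the replicate block reversed too (0.0320), and which ranged from −0.114 to 0.00565 with a library left out, highest without IRKO replicate 4. The border macrophage median was −0.956 with the stricter filter and ranged from −0.259 to 0.892 with a library left out, lowest without control replicate 2.

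With an estimated correlation camera called none of the 24 lists (fry called 21), and the adjusted p was 0.0577 for cholesterol and lipids, 0.123 for the tricarboxylic acid cycle, 0.403 for astrocytes, 0.521 for homeostatic microglia, neurons, endothelial cells and interferon response, and 0.528 for antigen presentation, cell cycle, choroid plexus, ribosomal proteins, disease-associated microglia, glycolysis, immediate early genes, inflammatory cytokines, oxidative phosphorylation and phagocytosis. Fry, which does not compare a list with other genes, passed border macrophages (0.0430), FOXO targets (0.0282), insulin signalling (0.0430), lymphocytes and red blood cells (0.0251) and oligodendrocyte precursors (0.0344), which camera did not, and missed immediate early genes (0.0736). Quantile normalization passed insulin signalling (0.0404) and lysosome (0.0423), and testing without a filter passed lymphocytes and red blood cells (0.0395). With each library left out in turn, camera's adjusted p ranged from 0.00324 to 0.0549 for antigen presentation, 0.00119 to 0.103 for cell cycle, 0.000468 to 0.189 for choroid plexus, 0.00764 to 0.0688 for disease-associated microglia, 2.16e-05 to 0.0967 for immediate early genes and 0.0312 to 0.243 for oligodendrocytes. The replicate block, which rests on replicates 1 and 2 of each group, changed no list call, but gave a lower oligodendrocyte median of 0.350. Of 161 named genes, 152 passed the threshold, and 16 of these lost it without at least 1 library, 13 of them without control replicate 2; the test against a fold of 1.2 and the replicate block each ended 6 calls, no variance trend 3, edgeR, DESeq2 and quantile normalization 2 each, 4 ended with edgeR and 3 with DESeq2 when IRKO replicate 1 was left out, no filter ended 1, and the microglia list scaling 49, of which 22 are among the 30 that it reversed and 27 did not change sign. Depth limits the genes with under 10 normalized counts in a group, and n = 2 in the controls limits every comparison.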

Other observations

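The 3 gene lists of the first 2 paragraphs, the liver marker list, the microglia list scaling and the tests of explanations in this part were chosen after the results they measure had been seen. Most connective tissue and bone genes were higher in IRKO. Of 21 tested genes 17 rose and 2 fell, with a median log2 change of 1.98, while 10 rose without control replicate 2 and 8 rose and 3 fell with libraries scaled to the homeostatic microglia list (median 0.58). The mean log2 value of the list was 6.87 and 6.61 in the controls and 7.78 to 9.31 in IRKO, highest in IRKO replicate 3. Col1a1 and Col1a2, the chains of type I collagen, rose by 3.08 ± 0.423 and 2.07 ± 0.323 (SE, n = 2 against 4), and Fn1, fibronectin, by 1.92 ± 0.574. Without control replicate 1 or 2 the limma call of Fn1 was lost (adjusted p = 0.0763 and 0.123), and in the microglia list scaling those of Fn1 (0.357) and Col1a2 (0.0725). The genes did not share 1 order of libraries, as Lox had 405 normalized counts in IRKO replicate 1 and 1349 in replicate 3 but 104 and 108 in replicates 2 and 4, whereas Bglap was lowest in replicate 1 (55.5 against 275 to 523). Bglap, the osteocalcin gene, rose by 4.14 ± 0.896 (2.90 without control replicate 2, adjusted p = 0.0604), while Dmp1, also known from bone, fell (−4.40 ± 0.266).

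All 16 genes of a list for handling glutamate, GABA and glycine fell. Their median was −3.30, or −3.21 without control replicate 1 and −3.34 without control replicate 2. Besides transporters and enzymes, the list holds the glutamate receptor Grm3 and the potassium channel Kcnj10. The astrocyte list also holds 4 of its genes, so the 2 lists are not independent. Slc6a11, a GABA transporter, changed by −4.36 ± 0.384, Gldc of the glycine cleavage system by −4.75 ± 0.152 and Kcnj10 by −3.65 ± 0.254 (SE, n = 2 against 4). Glutathione and antioxidant genes fell in 17 and rose in 1 of 22 cases, with a median of −0.90, or −2.33 in the microglia list scaling. Gstm1 (−4.59 ± 0.125), Prdx6 (−4.17 ± 0.146) and Nqo1 (−2.62 ± 0.240) fell, Gpx1 rose as deposited (0.74 ± 0.160) and turned to −0.69 in that scaling, and Gpx4 (−0.12 ± 0.156) did not pass limma's test as deposited. The changes of Gstm1, Prdx6, Nqo1, Slc6a11, Gldc and Kcnj10 lay within the range of the astrocyte markers (−5.13 to −2.07). Those of Gpx1 and Gpx4 lay above that range. Whether these transcripts came from microglia was not measured.

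Astrocyte transcripts differed widely between the groups, from Apoe at 378600 ± 18600 against 23050 ± 5780 normalized counts to Slc1a2 at 165200 ± 21900 against 11150 ± 1540 (SD, n = 2 and 4). Unspecific whole-brain RNA as the whole source would raise neuronal and astrocyte markers alike in the controls. Their medians, however, lay 4.88 apart as deposited (neurons 0.99), against an SD of 0.71 and 0.81 among members. The microglia list scaling shifts all genes alike, so the gap of 4.89 there (neurons −0.44) adds no support. None of the scalings run removed the astrocyte fall, since the astrocyte median reached at most −3.42 under the 3 other scalings. Among these the microglia list scaling lowers all genes in IRKO, so only TMM and quantile normalization could have shrunk the fall. Correlations between groups of at most 0.887, below the 0.972 or more within each, argue against an exchange of single libraries between the groups. They would be the same had the names of the whole groups been exchanged. Astrocyte RNA in the control precipitates, which pulling down tagged microglial ribosomes should remove, stays open as a hypothesis that the falls of the 25 markers (−2.07 or lower) raised and therefore do not test; of these markers 1 belongs to another of the 24 lists and 4 to the transmitter handling list. A change of these transcripts within microglia on loss of the receptor (median −3.89) would start from the level in the controls. There the mean log2 value of the astrocyte list (13.99 and 13.64) lay above that of the homeostatic microglia list (10.81 and 10.54). Microglial RNA alone would put astrocyte markers below microglial genes, so these values argue against such a change as the whole source. A partial change within microglia cannot be told apart from astrocyte RNA, because each genotype has its own libraries. In the IRKO libraries the astrocyte list lay below the homeostatic microglia list (9.82 to 10.22 against 11.8 to 12.23). Changes of the other lists in this comparison may carry the same difference in cell content.

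Blood and liver transcripts were concentrated in the controls, and above all in control replicate 2. All 5 erythroid genes were higher in both controls than in any IRKO library, so blood RNA in the control samples stays open, as a hypothesis raised by these genes and not tested on others. Of the 25 liver markers outside the named genes 25 were higher in control replicate 2 than in replicate 1, with a median ratio of 16.6, so liver RNA in that library is a candidate source, although the labels name only brain. A single shared source is argued against, as the ratio of control replicate 2 to 1 was 5.98 times larger for liver markers (12.8) than for erythroid genes (2.14). An effect of the genotype on blood content was not tested separately from the groups.

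The lower Insr value could reflect deletion in microglia or a loss of other RNA that carries Insr. Astrocyte RNA as the only carrier of Insr is argued against, since Insr fell less than the astrocyte marker that fell least, by a log2 difference of 1.37 (SE of the Insr change 0.135). Relative to the median of all genes Insr changed by −0.72, and 21% of tested genes fell further, so its fall does not by itself point to deletion. Deletion and a partial share of astrocyte Insr cannot be told apart, because the level of Insr in each cell type was not measured here.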
